A study of Mus musculus with 6 samples.

How the data were processed

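RNA was measured on 6 single-channel Affymetrix arrays, 3 from wild-type and 3 from Ets1-/- mice. Per the labels, the cells were CD4+CD8+ double-positive thymocytes of C57BL/6 mice aged 5 to 6 weeks, taken with magnetic beads first against CD8 and then against CD4 after formaldehyde crosslinking, and RNA was isolated with TRIzol. The labels describe litter-mate cohorts as the biological replicates, so p-values measure the spread among these samples; whether each array held 1 animal or several is not given in the sources used here.

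The deposited table holds log2 values for 41345 probe sets on the 6 arrays. The log2 scale was read from the values, which run from -15.86 to 16.36, with 1.63% of them below 0. Per the submitters' processing notes the tool was affy, with no version; the background correction, the normalization between arrays and the genome build are not given in the sources used here. The arrays had not been brought to 1 common distribution in the deposited log2 values: the medians were 4.21, 4.25 and 4.33 for wild-type replicates 1 to 3 and 3.66, 4.31 and 4.19 for Ets1-/- replicates 1 to 3. The interquartile range lay between 2.50 and 2.66. No probe set was identified as a control in the table of probe names, so no probe set was left out as a control, and the difference between 3' and 5' control probe sets was not analysed here. A block of 5333 probe sets had IDs below the first ID in that table. What they measure is not given, so controls may remain among the probe sets tested. The array number limits the precision of every value.

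Probe sets were named through the table of platform annotation: 23521 named 1 gene, 1814 named several and 16010 were unnamed here. Of those naming 1 gene, 23328 were matched by gene identifier to the RefSeq gene table of GRCm38.p6, which was used only for names and for which genes neighbour each other; 0 symbols needed an update. Each of 22180 genes was represented by its brightest probe set over all arrays, without a filter on dim probe sets. For 1082 genes this meant a choice among several probe sets. Among the changed genes, 18 had several probe sets, 0 of these had a called probe set in the opposite direction, and in 15 at most 1 probe set was called when all probe sets were tested.

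Differences were fitted on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), as Ets1-/- minus wild type with no covariate, and p was adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. Errors given as SE are limma's moderated standard errors. Gene lists were tested with camera at a preset correlation of 0.01 over 34 lists with at least 3 measured members (22 lists of gene functions and stages and 12 lists of cell type markers), and again with an estimated correlation and with fry. The list of T-cell receptor loci had too few measured members for a test. Of the 687 list entries, 593 were measured. Fisher's exact test compared genes near Ets1 with the others. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

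The text names Ets1, the 12 largest rises and 12 largest falls by log2 fold change among genes past the threshold whose groups did not overlap (genes named only by clone, Riken or Gm numbers were skipped), up to 4 members with the smallest p in each described list, up to 6 changed genes near Ets1, and a fixed set of genes whatever their result, among them Cd4, Cd8a, Cd8b1, Rag1, Rag2, Bcl2l1, Dntt, Ptcra, Il7r, Runx1, Tcf7, Gata3, Ets2, Fli1, Elf1 and Gabpa. Samples, lists, tests, alternatives and this rule were fixed before the data were examined. Rag1 and Tcf7 had no probe set naming them alone and were not analysed here.

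Alternatives chosen beforehand were the mean of all probe sets of a gene, filters at the median and 75th percentile of all probe sets, quantile normalization, median centring, cyclic loess, an intensity trend with a robust prior, array weights, no variance moderation, a replicate block, a pseudocount of 16 on the linear scale, and the omission of each array in turn. The choice among probe sets by an ID ending was not run, because the IDs carry no such ending. Added after seeing the data were a test of gene families by the start of their symbols, second lists of macrophage and of B-cell and plasma-cell genes, quantile normalization together with the pseudocount of 16, and a count without immunoglobulin genes and cell type markers.

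The fit was tested on simulated data: in 20 runs over 22180 genes with the wild-type means and the residual spreads, 200 genes per run were changed. For this comparison, 43.5% of genes changed by 2 on the log2 scale were recovered and 1.0% of genes changed by 1, and 3.37% of the calls were wrong. Fewer genes were changed per run than the 413 called in the real data, which makes the adjusted threshold stricter. The recovered shares can therefore understate recovery in the real data. A cell cycle list shifted by -0.50 was called in all 20 runs, with spread drawn independently for each gene, which real lists do not have.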

Results

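Gene expression was compared between double-positive thymocytes of wild-type and Ets1-/- mice, with 3 arrays in each group. Double-positive thymocytes are the immature T cells of the thymus that carry both CD4 and CD8, and Ets1 is a transcription factor of the ETS family expressed in lymphocytes. The comparison asks which transcripts depend on Ets1 at this stage. Spearman correlations over genes were 0.936 to 0.959 within groups and 0.890 to 0.925 between them. On the first principal component of the 6246 brighter genes, which held 62.5% of the variance, the groups did not overlap. The values of replicate 1 of Ets1-/- were shifted downwards, with a median of 3.66 against 4.19 to 4.33 on the other arrays.

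The targeted gene was examined first. Ets1 had a single probe set naming it alone, and its signal was 9.20 ± 0.11 (SD, n = 3) in wild type and 9.09 ± 0.27 (SD, n = 3) in Ets1-/-. The log2 fold change was -0.10 ± 0.23 (SE; 95% interval -0.65 to 0.44) with a limma adjusted p of 0.860. An exact permutation test gave p = 0.8, where 0.1 is the smallest p that 3 arrays against 3 allow. The part of the gene that the probes cover relative to the deletion is not given in the sources used here, so this signal does not check the labels, and directions below refer to the arrays labelled Ets1-/-. Among other ETS factors, Ets2 fell by 1.88 ± 0.24 (SE; adjusted p = 0.00811), from 9.95 to 8.07. Fli1, Elf1 and Gabpa did not pass the test, with log2 fold changes of 0.19, -0.05 and -0.40.

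In the arrays labelled Ets1-/-, macrophage, dendritic-cell and B-cell genes were higher together with some genes of mature T cells, while a smaller set including Ets2, Cd5, Tdrd5 and Plxnd1 was lower. Of 22180 genes, 287 were higher and 126 were lower (limma adjusted p under 0.05), and all 413 differed at least 2-fold. This size follows from the test, which could hardly call smaller changes. Top2a, for example, at -1.03 ± 0.22 (SE), did not pass it (adjusted p = 0.0674). In the simulated data 1.0% of genes changed by 1 on the log2 scale were recovered. That share can understate recovery here, because only 200 genes were changed per run. The 3 values of one group lay outside the range of the other for all 413 genes, and for 21.9% of all genes, where chance gives 10%. Over all probe sets, 269 were higher and 77 lower, together 346, and 112 to 202 were called when any 1 of the 6 arrays was left out. The median log2 fold change over all genes was -0.22, and -0.01 once arrays were centred on their medians. List medians in the Results are therefore given relative to that of all genes. Under other observations, medians are those of the log2 fold change itself unless said otherwise.

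The number of calls depended on single arrays: it was 262, 261 and 247 without wild-type replicates 1, 2 and 3, and 190 and 264 without Ets1-/- replicates 2 and 3. The number lower was 43, 38 and 44 without wild-type replicates 1, 2 and 3 and 45 without Ets1-/- replicate 2, and the number higher was 145 and 176 without Ets1-/- replicates 2 and 3. The share of higher genes among the calls was 69.5%, but 53.4% with a pseudocount of 16 (484 higher, 423 lower) and 55.9% with quantile normalization added to it (754 higher, 596 lower). Among genes above the 75th percentile of signal the balance turned, with 231 higher and 310 lower (42.7% higher).

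The 12 largest rises included 6 immunoglobulin genes and the chemokines Ccl24 and Ccl8. The chemokine Ccl24 rose from 4.88 ± 0.39 to 12.11 ± 0.56 (SD, n = 3 each; log2 fold change 7.24, adjusted p = 0.000224). The chemokine Ccl8 rose by 7.01 and Retnla, a protein secreted by alternatively activated macrophages, by 7.22. The ribonuclease Rnase2a rose by 6.77 and the actin-binding protein Cnn1 by 6.37. The light-chain segments Igkv4-72, Igkv4-91, Igkv9-120 and Iglv1 rose by 10.17, 7.35, 6.75 and 6.19, and the heavy-chain segment Igh-VS107 by 8.38. Matrix metalloproteinase Mmp13 and Igkv6-14 had nominal changes of 11.79 and 11.55 (adjusted p = 0.0499 and 0.0203), but their wild-type means were -4.80 and -6.48. With a pseudocount of 16 these became 3.11 and 1.71, the latter with an adjusted p of 0.0538. The pseudocount also lowered the changes of Igkv4-72 to 6.92, Igh-VS107 to 5.03, Igkv9-120 to 4.27 and Cnn1 to 3.75, so the sizes for genes with low wild-type signal depend on the low end of the scale.

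The largest falls were in genes of several functions. Lypd6b, a GPI-anchored Ly6-family protein, fell by 7.08 ± 0.46 (SE; adjusted p = 0.000578), from 9.91 to 2.83. The cyclic-nucleotide-gated channel Cnga1 fell by 6.81 ± 0.32 (adjusted p = 0.000224), from 9.77 to 2.96. The amino acid transporter Slc6a19 fell by 5.12, the synaptotagmin Syt13 by 4.77, Tmem108 by 4.09, Igsf23 by 3.99, the transcriptional coactivator Eya2 by 3.83 and the sodium pump subunit Atp1b1 by 3.80. Gsdma, F13a1 and Plxdc1 fell by 3.09, 3.02 and 2.93, and the cytokine Ltb fell from 7.92 to 4.92. With the pseudocount of 16 Gsdma, whose wild-type signal was only 4.02, fell by 0.85, and Eya2 fell by 2.01. Most of these genes had a low signal in Ets1-/-, so the sizes of the falls also depend on the low end of the scale: with the pseudocount Lypd6b fell by 5.38, Cnga1 by 5.20 and Syt13 by 3.48. Of the 24 genes in these 2 rankings, 5 lost their call when single arrays were left out. Mmp13 kept it only without wild-type replicate 1, with an adjusted p up to 0.158. Igkv6-14 lost it without wild-type replicate 2 or any 1 of the Ets1-/- arrays (up to 0.0869), and Slc6a19 kept it only without Ets1-/- replicate 3 (up to 0.151). Tmem108 lost it without wild-type replicate 1 or 2 or Ets1-/- replicate 1 or 2 (up to 0.0900), and Plxdc1 without wild-type replicate 2 or 3 or Ets1-/- replicate 2 (up to 0.0776).

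**Figure D1:**
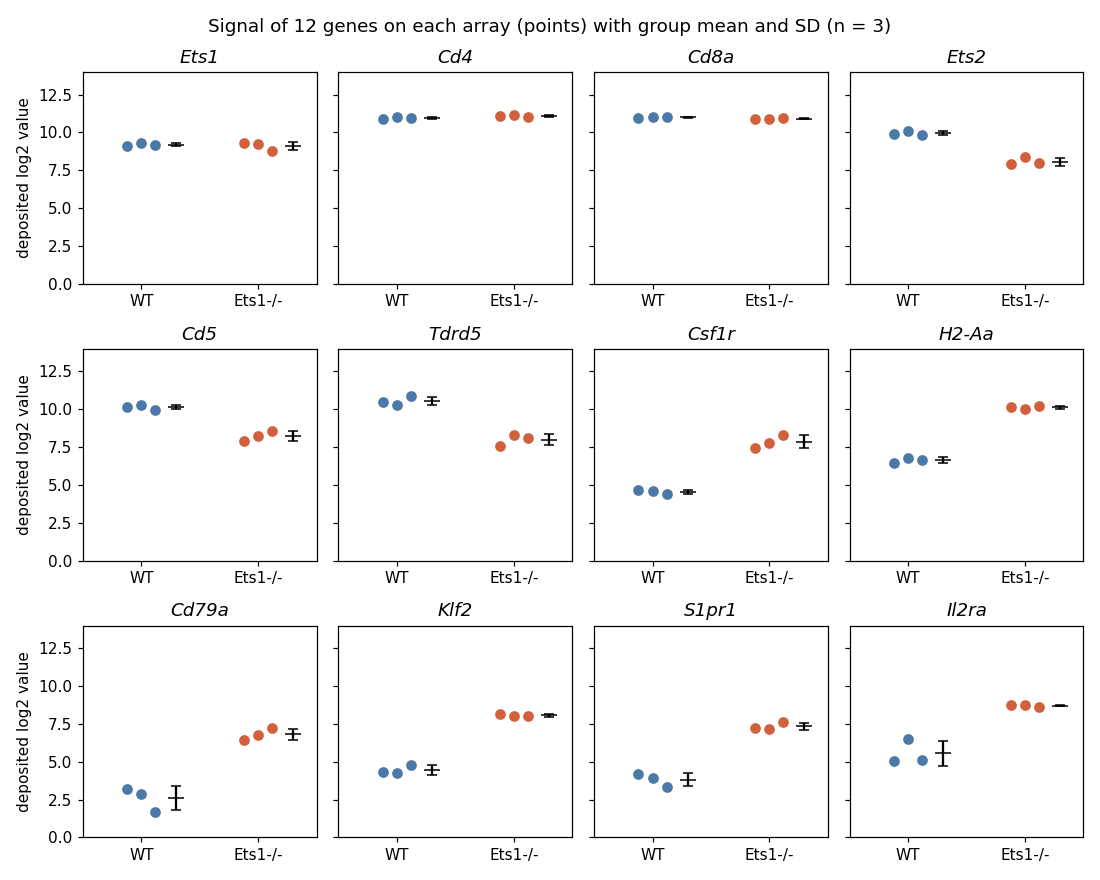
Deposited log2 value (vertical axis) of 12 genes on each array; points are single arrays of wild-type (blue) and Ets1-/- (orange) thymocytes, and the bars give the group mean and SD (n = 3). Ets1, Cd4 and Cd8a overlapped or lay close between groups, Ets2, Cd5 and Tdrd5 were lower in Ets1-/-, and the other genes were higher, such as H2-Aa at 6.64 against 10.12.

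Markers of macrophages and monocytes rose most uniformly of the lists. Of 17 measured members, 15 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change 2.99 above that of all genes (camera adjusted p = 1.52e-38, and adjusted p = 0.0425 with an estimated correlation). The growth factor receptor Csf1r rose from 4.55 ± 0.15 to 7.86 ± 0.44 (SD, n = 3 each; adjusted p = 0.00140), the protease Ctss by 2.78, the complement component C1qa by 2.85 and Mpeg1 by 3.05. Of 14 dendritic-cell markers, 6 rose and 0 fell (7 and 1 adjusted over the list alone), with a median 1.62 above all genes (adjusted p = 6.73e-15, and adjusted p = 0.0425 with an estimated correlation). They included the MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1, which rose by 3.48, 4.11 and 3.65, and the transcription factor Irf8, which rose by 2.51. The other 8 markers did not pass over all genes. Whether dendritic cells, or the macrophages or B cells whose lists also rose, gave these rises was not tested. Of 12 B-cell markers, 5 rose and 0 fell (10 and 0 adjusted over the list alone), with a median 2.15 above all genes (adjusted p = 1.72e-18, and adjusted p = 0.0425 with an estimated correlation). The receptor component Cd79a rose by 4.20, Fcrla by 3.05 and the B-cell factor Ebf1 by 2.08. Ms4a1, which encodes CD20, rose by 6.14. All 4 had wild-type means of 2.60 or less, and with a pseudocount of 16 the changes were 2.51 for Cd79a, 1.51 for Fcrla, 2.39 for Ms4a1 and 0.65 for Ebf1, which lost its call (adjusted p = 0.0647). The call for Ebf1 held only without Ets1-/- replicate 2 among the fits that left out 1 array (adjusted p up to 0.100).

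Markers of most other cell types were not higher. Their signals were low, so a missing rise says little about whether such cells were present. Median wild-type signals were 3.46, 4.16, 3.98, 3.42 and 3.45 for the neutrophil, erythroid, epithelium, fibroblast and endothelium lists, where the median of all probe sets was 4.13. The lists for neutrophils (12 measured), erythroid cells (7), thymic epithelium (15) and fibroblasts (12) had 0 members past the test, over all genes and adjusted over the list alone, and camera adjusted p of 0.698, 0.312, 0.698 and 0.860. Their members with the smallest p were Ltf, Ngp, Mmp9 and Elane at -1.12, -1.02, -0.70 and -0.48, Car2, Rhd, Slc4a1 and Epor at -0.80, -0.54, -0.66 and -0.27, Cldn3, Foxn1, Dll4 and Krt18 at -1.12, -0.46, -0.53 and 1.10, and Col1a1, Fstl1, Pdgfrb and Pdgfra at -0.49, -0.52, -0.46 and -0.48. At an unadjusted limma p under 0.05 the counts were 1, 0, 1 and 0. The 12 endothelial markers had a median of -0.31 relative to all genes (adjusted p = 0.0192, but adjusted p = 0.497 with an estimated correlation), with 0 members past the limma test over all genes (4 at an unadjusted p under 0.05) and 2 lower adjusted over the list alone; the call ended with a pseudocount of 16 (adjusted p = 0.0635). Pecam1 and Eng had the smallest p, with log2 fold changes of -1.26 and -1.15, followed by Plvap at -0.66 and Emcn at -0.69, and Pecam1 was called with the pseudocount (adjusted p = 0.0277). The 9 natural killer markers had 0 members past the limma test over all genes (3 at an unadjusted p under 0.05) and 2 higher adjusted over the list alone (adjusted p = 0.128). Among them Klrd1, Il2rb, Prf1 and Gzma had values of 1.24, 4.08, -0.56 and 0.81. The value of Il2rb depended on single wild-type arrays: it was 2.61 without replicate 3, and 5.28 without replicate 2, where it was called (adjusted p = 0.0411). With a pseudocount of 16 Il2rb and Klrd1 were at 2.03 and 0.60 and were called (adjusted p = 0.00886 and 0.0340). The 9 gamma-delta T-cell markers had 2 that rose by either adjustment (adjusted p = 0.0219, but adjusted p = 0.372 with an estimated correlation). These were the transcription factor Maf, up by 3.46, and the kinase Blk, up by 2.99, which is also on the B-cell list; Il17a and Sox13 had values of 0.66 and -0.42. Maf lost its call without wild-type replicate 2 or Ets1-/- replicate 1 or 3 (adjusted p up to 0.101), and Blk kept it only without wild-type replicate 2 or Ets1-/- replicate 1 (up to 0.145). The wild-type mean of Blk was 0.79, and with a pseudocount of 16 its change was 0.80 and its call ended (adjusted p = 0.0852).

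The genes that define the double-positive stage were affected in part. The coreceptor genes Cd4, Cd8a and Cd8b1 had log2 fold changes of 0.13 ± 0.21, -0.09 ± 0.20 and -0.03 ± 0.21 (SE), with adjusted p of 0.794, 0.863 and 0.953. Rag2, which with Rag1 cuts receptor genes, was at -0.29 ± 0.21, the survival gene Bcl2l1 at 0.11 ± 0.25 and the terminal transferase Dntt at -0.46 ± 0.20 (adjusted p = 0.389). In this list of 21 measured genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone). The tudor-domain gene Tdrd5 fell by 2.55 ± 0.28 (SE; adjusted p = 0.00402), the plexin Plxnd1, a guidance receptor of thymocytes, by 2.78 ± 0.30 (adjusted p = 0.00406), Ets2 by 1.88 and Endou by 2.24. The camera adjusted p was 0.00933 downwards, but adjusted p = 0.372 with an estimated correlation, and fry gave an adjusted p of 0.00474. The list's mean was -0.48 relative to the mean of all genes, while its median was 0.00 above theirs. The list's call also ended without Ets1-/- replicate 3 (adjusted p = 0.102). Endou lost its call without Ets1-/- replicate 2 or any wild-type array (adjusted p up to 0.100).

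Of 28 T-cell receptor signalling components, 1 was called. Cd5, an inhibitory coreceptor whose level follows receptor signal strength, fell by 1.90 ± 0.25 (SE; adjusted p = 0.00937), from 10.13 to 8.22, with an adjusted p of 0.0509 without Ets1-/- replicate 2. Cd6, Fyn and Zap70 had values of -1.41, -0.91 and -1.37 with adjusted p of 0.0712, 0.0957 and 0.127, and all 3 were called lower with a pseudocount of 16 (adjusted p = 0.0207, 0.0108 and 0.0419). Adjusted over the list alone, 8 members fell and 1 rose; camera gave an adjusted p of 0.180 for the list and fry 0.0432. Of 22 genes induced by receptor signals, Cd5 fell and Irf4 rose by 2.13 (6 higher and 3 lower adjusted over the list alone). The adjusted p of this list was 0.00164, but adjusted p = 0.372 with an estimated correlation, and it was 0.0671 among genes above the median signal. Ikzf2 and Dusp2 had values of 1.02 and -1.30 without passing the test, which both passed with the pseudocount (adjusted p = 0.00687 and 0.0324). Irf4, a lymphocyte factor also made by B and dendritic cells, lost its call without wild-type replicate 2 or 3 or Ets1-/- replicate 2 or 3 (adjusted p up to 0.0842), and its change was 0.94 with a pseudocount of 16.

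Some genes of mature T cells were higher. Of 22 single-positive maturation genes, 7 rose and 0 fell (10 and 2 adjusted over the list alone), with a median 0.89 above all genes (adjusted p = 1.48e-09, but adjusted p = 0.0766 with an estimated correlation). Fry gave the list an adjusted p of 0.00672. Of the members, 12 lay above 0 and 10 below, and 17 lay above the median of all genes. Whether thymocytes or other cells whose markers rose gave the rises here and in the lists that follow was not tested. The transcription factor Klf2, which drives exit from the thymus, rose from 4.46 ± 0.31 to 8.07 ± 0.09 (SD, n = 3 each; adjusted p = 0.000578). Its target S1pr1, the receptor through which T cells leave the thymus, rose by 3.54 ± 0.28 (SE; adjusted p = 0.00110). Ms4a4b and the GTPase Gimap3 rose by 2.94 and 3.07. Gimap3 lost its call without wild-type replicate 2 or any 1 of the Ets1-/- arrays (adjusted p up to 0.107). The overlapping marker list of mature single-positive T cells had 4 of 16 higher and 0 lower (6 and 1 adjusted over the list alone; adjusted p = 6.26e-08, and adjusted p = 0.0425 with an estimated correlation). Il7r, the interleukin-7 receptor, had 4.67 ± 0.57 in wild type and 6.67 ± 0.68 in Ets1-/- (SD, n = 3 each; limma adjusted p = 0.0663), and was called with a pseudocount of 16 (1.50, adjusted p = 0.0293).

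Cytotoxic and innate-like genes were higher as well, with 5 of 25 that rose and 0 that fell (9 and 0 adjusted over the list alone; adjusted p = 8.67e-11, and adjusted p = 0.0425 with an estimated correlation). Granzyme Gzmb rose by 4.53 ± 0.29 (SE; adjusted p = 0.000578), Nkg7 by 3.23, the chemokine Ccl5 by 3.41 and the Fc receptor chain Fcer1g, which myeloid cells share, by 2.65. With a pseudocount of 16 the change of Gzmb was 2.56. Among 14 genes of MHC class I presentation, H2-K1 rose by 2.01 (7 higher and 0 lower adjusted over the list alone; adjusted p = 2.24e-11, and adjusted p = 0.0425 with an estimated correlation). H2-M3, Nlrc5 and Psmb9 had values of 1.10, 1.44 and 0.73 without passing the test. H2-M3 was called without Ets1-/- replicate 1 (adjusted p = 0.0395) and, like Psmb9, with a pseudocount of 16 (adjusted p = 0.00886 and 0.0448).

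Genes of the earlier double-negative stage gave a mixed picture. Of 23 measured, 6 rose and 0 fell (13 and 1 adjusted over the list alone), with a median 1.72 above all genes (adjusted p = 6.73e-15, but adjusted p = 0.0597 with an estimated correlation). By fry the adjusted p was 0.0133. The interleukin-2 receptor chain Il2ra rose by 3.17, from 5.55 to 8.71, and the adhesion receptor Cd44 by 2.14. Mef2c and Spi1, transcription factors that B and myeloid cells also express, rose by 3.63 and 3.17, and were 2.27 and 1.91 with a pseudocount of 16. Ptcra, the pre-T-cell receptor chain, rose by 1.50 ± 0.25 (adjusted p = 0.0282) but held its call only without Ets1-/- replicate 1 when single arrays were left out (up to 0.116). The marker list of early double-negative thymocytes had 4 of 14 higher and 0 lower (8 and 1 adjusted over the list alone). Its adjusted p was 1.69e-10 by camera, but 0.0999 by camera with an estimated correlation, and 0.0244 by fry. Of 15 Notch targets, Il2ra, Ptcra and Myc rose, Myc by 1.64 (4 higher and 3 lower adjusted over the list alone; adjusted p = 0.0205, but adjusted p = 0.497 with an estimated correlation), and Hes1 had a value of 3.04 with an adjusted p of 0.0511. Hes1, with a wild-type mean of 1.43, was called without wild-type replicate 1 (3.73, adjusted p = 0.00667) and with a pseudocount of 16 (0.99, adjusted p = 0.0138). The call of Myc was lost without any 1 of the 6 arrays (adjusted p up to 0.148), and that of the Notch list without Ets1-/- replicate 1 (adjusted p = 0.0620) and under quantile normalization (0.0629), median centring (0.0677), cyclic loess (0.0722), array weights (0.0622) and the filters on dim genes (0.227 and 0.403).

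Cell cycle genes were lower as a group: 33 of 34 lay below the median of all genes, and the list's median was -0.85 relative to it (adjusted p = 2.24e-11, but adjusted p = 0.372 with an estimated correlation, which was 0.721 among the members). Over all genes 1 member fell and 1 rose, and adjusted over the list alone 25 fell and 1 rose. The spindle checkpoint kinase Bub1b fell by 1.56 ± 0.26 (SE; adjusted p = 0.0258), kept only without Ets1-/- replicate 1 when single arrays were left out (up to 0.107). Topoisomerase Top2a and cyclin Ccnb2 had values of -1.03 and -1.26 with adjusted p of 0.0674 and 0.0711, and both were called lower with a pseudocount of 16 (adjusted p = 0.00464 and 0.0125). Cyclin Ccnd2 rose by 2.32 ± 0.27 (adjusted p = 0.00602). The cell cycle inhibitor Cdkn1a rose by 4.47 ± 0.47 (adjusted p = 0.00353; 3.41 with a pseudocount of 16), as the 1 member of 16 p53 targets that was called over all genes (1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.180), while Fas, Ccng1 and Trp53inp1 were at -1.10, 0.45 and -0.32. Fas was called with the pseudocount (adjusted p = 0.0294).

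Several further lists were called higher by camera at the preset correlation and not with an estimated one. Of 22 interferon-stimulated genes, Oasl2 and Bst2 rose by 3.64 and 1.54 (5 higher and 0 lower adjusted over the list alone; adjusted p = 1.08e-09, but adjusted p = 0.165 with an estimated correlation), and Irf7 and Gbp3 were at 1.96 and 2.24. Of 21 immediate early and heat shock genes, the chaperone Hspa1a and the AP-1 factor Fosb rose by 4.06 and 1.57 (4 and 0 adjusted over the list alone; adjusted p = 5.46e-10, but adjusted p = 0.0999 with an estimated correlation), Hspa1b was at 2.83, and Jun had 4.65 in wild type and 6.65 in Ets1-/-. With a pseudocount of 16 Oasl2, Hspa1a and Fosb were at 1.98, 1.60 and 0.70, Hspa1b was at 1.44 (adjusted p = 0.0795), and Irf7 and Gbp3 were at 1.39 and 1.23 and were called (adjusted p = 0.0172 and 0.0143). Stat4, Cflar and Birc2, named with the lists that follow, were called with it as well (adjusted p = 0.0159, 0.00472 and 0.0468). Fry also called the immediate early and heat shock list (adjusted p = 0.0493). Of 22 cytokine receptor and signalling genes, Il2ra and Socs2 rose (8 and 1 adjusted over the list alone; adjusted p = 0.000153, but adjusted p = 0.372 with an estimated correlation), and Stat4 was at -1.51. Among genes above the 75th percentile of signal the list's adjusted p was 0.471. The change of Socs2, a cytokine signalling inhibitor, was 5.20, and 1.03 with a pseudocount of 16. Of 27 T-cell transcription factors, Id2 rose by 1.55 (2 and 0 adjusted over the list alone; adjusted p = 0.00423, but adjusted p = 0.372 with an estimated correlation), while Ikzf3, Tox, Runx1 and Gata3 were at 0.51, 0.41, -0.29 and -0.08. This list's call ended under quantile normalization (adjusted p = 0.0900), cyclic loess (0.0722) and the 75th percentile filter (0.109). Of 18 BCL2 family genes, Bcl2a1a rose by 2.95 (1 and 1 adjusted over the list alone; adjusted p = 0.0423, but adjusted p = 0.497 with an estimated correlation), and Cflar, Bid and Birc2 were at -0.88, -0.80 and 0.56. That list's call ended under every other setting (adjusted p from 0.0543 to 0.209), the omission of wild-type replicate 1 or 3 or Ets1-/- replicate 1 or 3 among them (up to 0.151), except without wild-type replicate 2 or Ets1-/- replicate 2. The call of the gamma-delta markers ended without Ets1-/- replicate 1 (adjusted p = 0.0771) and with median centring (0.0508). Bst2 and Id2 kept their calls only without Ets1-/- replicate 1 (up to 0.0933 and 0.0869), Fosb only without wild-type replicate 3 or Ets1-/- replicate 1 (up to 0.0869), and Socs2 only without wild-type replicate 1 or 2 (up to 0.0933).

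The remaining lists were not called by camera. Of 19 chemokine receptors and homing genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.117). S1pr1 and the integrin chain Itgae, up by 2.96, stood against Plxnd1 and the integrin chain Itgal, down by 1.80. Of 25 ETS family genes, Spi1 rose and Ets2 and Elk3 fell, Elk3 with a log2 fold change of -1.46 (4 and 2 adjusted over the list alone; adjusted p = 0.144), and Spib was at 3.33 with an adjusted p of 0.0578, and at 1.71 with a pseudocount of 16 (adjusted p = 0.0247). Of 16 glycolysis genes, the kinase Pdk1 fell by 1.65 (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.312), and Slc2a3, Ldha and Aldoc were at -1.43, -0.51 and -0.76. Over all genes 0 members passed among 14 recombination genes (adjusted p = 0.860), 21 ribosome biogenesis genes (0.133), 15 cholesterol synthesis genes (0.312) and 4 sex-linked genes (0.312), with 1, 1, 1 and 0 at an unadjusted limma p under 0.05. Adjusted over the list alone, 0 passed except 1 lower ribosome biogenesis gene. Their leading members were Polm, Hmgb2 and Prkdc at 0.93, -0.40 and -0.38, Wdr12, Rrp12, Mybbp1a and Wdr43 at -1.40, 0.73, 0.61 and 0.42, Sc5d, Lss, Sqle and Insig1 at -0.74, 0.49, -0.47 and 0.35, and Kdm5d, Eif2s3y, Xist and Uty at -0.35, 0.34, 0.60 and -0.12. For the receptor signalling, recombination, glycolysis and epithelium lists the test pointed down while the median lay 0.04, 0.04, 0.07 and 0.00 above that of all genes. Wdr12 was called with a pseudocount of 16 (adjusted p = 0.00872) and when Ets1-/- replicate 1 was omitted (adjusted p = 0.0330), and Slc2a3 when Ets1-/- replicate 3 was (adjusted p = 0.0487). Elk3 lost its call without any 1 of the 6 arrays (up to 0.172), Pdk1 kept it only without Ets1-/- replicate 1 (up to 0.103), and Itgal only without Ets1-/- replicate 1 or 3 (up to 0.0683).

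**Figure D2:**
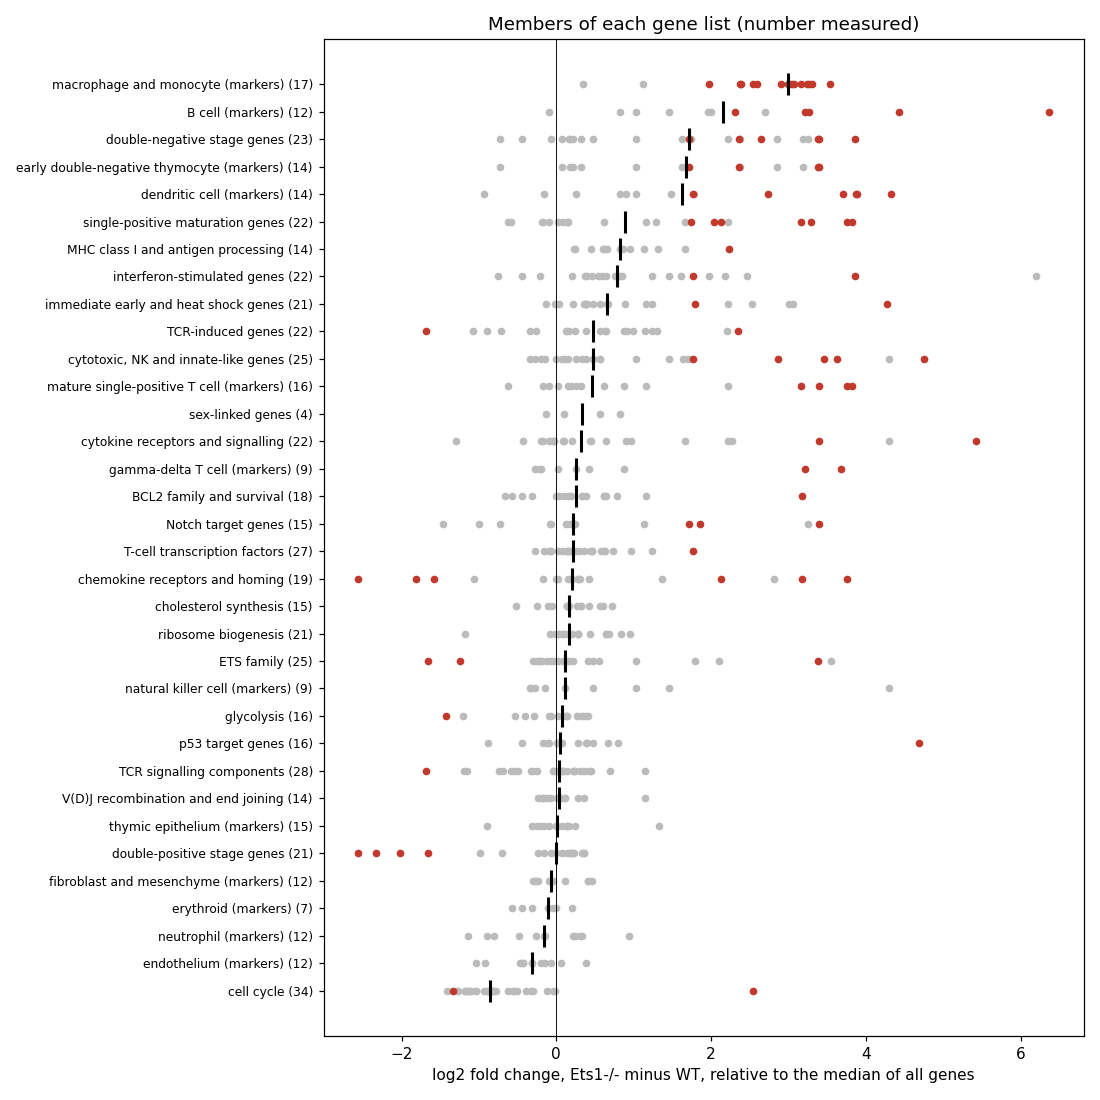
Log2 fold change of each measured list member relative to the median of all genes (horizontal axis, Ets1-/- minus wild type, 3 arrays each) for the 34 lists; red points passed the limma test over all genes, grey points did not, and black marks are list medians. Macrophage markers sit highest with a median of 2.99 and the cell cycle list lowest with a median of -0.85.

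Genes near Ets1 were examined apart, because an allele can carry flanking sequence of another strain. Within 10 Mb of Ets1, 0 of 210 genes were called by limma, although 20 had an unadjusted p under 0.05, against 411 of 21781 genes elsewhere (1.89%; Fisher's exact test, two-sided, p = 0.0363). In a 5 Mb window 0 of 68 were called (Fisher's exact p = 0.641), and camera found no shared shift of the 10 Mb set (p = 0.944). The shortfall did not hold among genes above the median signal, where the odds ratio was 1.36 (Fisher's exact p = 0.543). Above the 75th percentile it was 0.456 (Fisher's exact p = 0.717). When single arrays were left out the odds ratio stayed at 0 in 5 of 6 fits and was 0.272 without Ets1-/- replicate 1, with fewer calls and a Fisher's exact p from 0.181 to 0.431.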

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

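Probe sets without a single named gene entered no gene-level comparison, and some of them gave more signal in the arrays labelled Ets1-/- than in wild type (limma adjusted p under 0.05 over all probe sets). Of the 16010 probe sets with no gene named, which may include controls, 78 were higher and 26 lower. Of the 1814 that name several genes, 19 were higher and 2 lower. Groups of 3 arrays are too small for the test of single outlying samples used for larger groups, so it was not run.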

How the results depend on the processing

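Quantile normalization with the pseudocount, and the omission of immunoglobulin and marker genes, were chosen after the result was seen. All 413 changed genes kept their sign under every alternative that tested them, and 0 of 73 named genes called reversed; 12 were called under every setting and 51 in all 6 fits that left out 1 array. Of 81 named genes not called, 33 passed under at least 1 setting and 22 with the pseudocount. Of 20 called lists, 12 were called under every setting that ran camera at the preset correlation and 0 reversed. For the shifts below the cause was not tested, except that filters and omitted arrays reduce the number of genes or arrays tested. Low signal over background limits how well fold sizes are known: 1.63% of values were below 0, which inflates folds against them.

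The count of changed genes (413; 287 higher, 126 lower; all at least 2-fold) was 798 with quantile normalization (513 higher, 285 lower; 706 at least 2-fold), 745 with median centring (545, 200; 708), 777 with cyclic loess (541, 236; 693), 1172 with the intensity trend (618, 554; 886), 1019 with array weights (625, 394; 859), 56 without moderation (37, 19; 45), 907 with the pseudocount (484, 423) and 1350 with quantile normalization and the pseudocount (754, 596). The number lower was 264 and 310 with the filters at the median and the 75th percentile; with the latter, 42.7% of calls were higher. Without immunoglobulin and marker genes 322 genes changed. Leaving out single arrays gave 190 to 379 changed genes, 145 to 276 higher and 38 to 103 lower. Changed probe sets (346) numbered 588 and 571 with the filters, 580, 593, 914, 625, 70 and 763 with quantile normalization, loess, trend, weights, no moderation and pseudocount, 1228 with quantile normalization and pseudocount, and 112 to 202 without single arrays.

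The labels do not say whether equal replicate numbers pair the samples, and deviations of same-numbered arrays, which correlated at -0.07, -0.01 and -0.05, gave no sign of it. With the replicate block 311 genes were called (249 higher, 62 lower), 278 of them among the 413; 10 named genes lost their call and 2 gained one. It also called 48 probe sets and 19 lists. The near-Ets1 odds ratio stayed at 0 under the block (Fisher's exact p = 0.127).

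Ets1 itself was 0.11 with median centring and ranged from -0.19 to 0.049 without single arrays, never past the threshold. Of the lists, 13 were called with the 75th percentile filter, 6 with an estimated correlation, 12 by fry in 1 direction and 27 in either direction. The odds ratio of genes near Ets1 was 0 and became 1.36 with the median filter (Fisher's exact p = 0.543). It was 0.456 with the 75th percentile filter, 0.274 with median centring, 0.605 with array weights, 0 without moderation, 0.569 with the pseudocount, 0.449 with quantile normalization and pseudocount, 0 in the 5 Mb window, and 0 to 0.272 without single arrays, each with p above 0.05. The odds ratio was 0.255 with quantile normalization, 0.262 with cyclic loess, 0.345 with the intensity trend and 0.324 in the 20 Mb window. For these the Fisher's exact p was 0.0378, 0.0370, 0.0281 and 0.0392. The choice of probe sets by ID ending was not run.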

Other observations

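The tests of scaling, dilution, other stromal cells, array swaps and the second B-cell list were chosen only after the result was seen, as were the symbol families.

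Immunoglobulin light-chain segments stood out among gene families defined by the start of their symbols. Of 13 measured Igkv genes, 9 rose and 0 fell, with a median log2 fold change of 5.32 (Fisher's exact test, one-sided, adjusted p = 2.12e-12 over 346 families). CC chemokines had 5 of 19 higher and 0 lower (adjusted p = 0.000401) and CXC chemokines 3 of 13 higher and 0 lower (adjusted p = 0.0385). Genes whose symbols start with Ms and then a digit, such as Ms4a1, had 5 of 20 higher and 0 lower (adjusted p = 0.000401). CD antigens (symbols starting with Cd and then a digit) had 9 of 91 higher and 1 lower (adjusted p = 0.000401). In the other direction, 0 of the 346 families passed, with calcium/calmodulin kinase genes (Camk) nearest at 2 of 10 lower (adjusted p = 0.484). The plasma-cell genes Jchain and Mzb1 rose by 5.30 and 3.95; these were chosen after their values were seen.

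The joint rise of macrophage, dendritic-cell and B-cell genes may reflect other cells in the sorted fraction, although the beads against CD8 and CD4 would remove most cells that carry neither. A second list of 30 measured macrophage genes, none of which had been looked at when it was written, had a median log2 fold change of 1.34. Of its members 11 were higher, 0 lower and 25 above 0, as macrophages in the fraction would need. The explanations left open below would give the same rise, so the list does not separate them. Of the 30, 17 had a wild-type signal above the median of all probe sets and 0 were on another list. The abundant Ctsb rose by 1.79 and Lyz2, Apoe and Ctss reached 9.86, 10.24 and 9.88 in Ets1-/-. In contrast Ctsd and Laptm5, with wild-type signals of 9.67 and 10.34, were at 0.20 and -0.07. The dimmer Cd163, Vsig4, Timd4, Marco and Gpnmb were at 0.16, -0.08, 0.04, -0.21 and -0.50. A second list held 25 B-cell and plasma-cell genes, 5 of them seen before (Ly86, Cxcr5, Mzb1, Jchain and Bach2) and 2 on another list. Its median log2 fold change was 0.97 with 5 higher and 24 above 0, which lies between the bounds set and does not decide. Relative to all genes its middle member Fcrl1 was at 1.19, so this outcome depends on the measure. The tables argue against array scaling, since the macrophage list's median stayed at 2.13 or more over the other scalings and without each array. For scaling this was near settled beforehand, because the array medians ran only from 3.66 to 4.33. A lower share of double-positive cells that raises every other type alike cannot be told apart from these data. The 39 fibroblast, endothelial and epithelial markers had a median log2 fold change of -0.31, not relative to all genes. Their median signal of 3.47 lay below the 4.13 of all probe sets, so they do not decide. Expression of these genes by Ets1-/- thymocytes themselves, or a changed thymus composition in these mice, stays open and untested.

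The lower cell cycle genes could come from array 1 of Ets1-/- or from scaling, but without that array the list's median log2 fold change was -0.82, and over the other scalings it was at most -0.86. The scaling result was near settled beforehand, since the list's median was already -0.85 relative to all genes. Dilution of double-positive cells would lower Rag2 and Dntt as much, and the lower bounds of their 95% intervals were -0.77 and -0.93, above the list's median of -1.07. That median has a spread of its own, and the bounds did not lie above it without wild-type replicate 1 (-0.97 and -1.11 against -0.96). Nor did that of Dntt without Ets1-/- replicate 1 (-0.85 against -0.82), so Rag2 and Dntt do not decide. Cd4, Cd8a and Cd8b1, at 0.13 ± 0.21, -0.09 ± 0.20 and -0.03 ± 0.21 (SE), argue against dilution of this size by cells without these transcripts. In the double-positive list, with a median log2 fold change of -0.22, 4 members were called lower and fell further. Dilution stays open, also by cells that carry Cd4 or Cd8. The members' correlation of 0.721 leaves the group difference itself uncertain, since with it the adjusted p was 0.372. A smaller share of dividing cells in Ets1-/- is one hypothesis that stays open, and no test here separates it from a difference among the 6 samples in cycling.

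The Ets1 signal was not lower in the arrays labelled Ets1-/-. A swap of 2 arrays between the groups, or a single array carrying the other group's label, is argued against by the correlations: every array correlated better with its own group, by at least 0.0261 (mean Spearman within minus between). An exchange of the labels of all 6 arrays would leave these correlations as they are and stays open. Where the probes lie relative to the deletion, and whether a transcript remains, stays open and was not tested.

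With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 413 genes, with 1 as the highest of the other splits. The counts of genes at least 2-fold were the same 413 and 1, because they hold the same genes, and add no separate evidence. For probe sets the real split gave 346, where the highest other split gave 7. In each of these 3 counts 1 of the 10 splits was as large, the real one. For gene lists at the preset correlation, the real split called 20 and another split, wild-type replicates 1 and 3 with Ets1-/- replicate 2 against the rest, also called 20, so 2 of 10 splits were as large. With an estimated correlation the real split called 6 lists and each of the others 0. Every other split mixes wild-type and Ets1-/- arrays, so a difference between the groups adds to its residual spread. Low counts of genes, probe sets and these lists there were thus near settled beforehand and do not measure chance.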
